A study of Mus musculus with 6 samples.

How the data were processed

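Chromatin accessibility was measured by ATAC-seq in 3 control and 3 Lmna knockout samples of day 10 cardiomyocytes, sorted by a fluorescent Nkx2-5 reporter after hanging-drop differentiation of mouse embryonic stem cells. Groups and replicate numbers came from the sample titles. Per the labels' protocols, nuclei were permeabilised and tagmented and the fragments amplified and size selected with beads.

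The submitters' processing notes name Trimmomatic 0.39, Bowtie2, SAMtools, Picard 1.119, deepTools, MACS2, bedtools 2.28.0, DiffBind, DESeq2, ChIPseeker and the genome build mm10, with no roles or settings, so it is not given in the sources used here how reads were shifted, filtered or normalized, or whether peaks were called per sample. Per the submitters' processing notes, DESeq2 and DiffBind are among the tools the authors used, and the column names of the table are those DiffBind and ChIPseeker write. A single table of the authors' comparison was used, with 8 columns. Per the file headers, the deposited means over all samples and over each group and the deposited fold are on the log2 scale of normalized reads. The deposited fold equals the knockout mean less the control mean within 0.01 in all 65535 rows. The authors gave each region a p-value and an adjusted p-value. Region width and distance to the nearest transcript start were read as bp, as the file headers state no unit.

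The rows are ordered by p and stop at 65535, the last with an adjusted p = 0.843. From the last row, about 80900 regions were tested and 19.0% of them, all with higher p, are not analysed here. All regions past the threshold are therefore present, but any background of unchanged regions is incomplete and leaves few folds near 0, so medians of weakly shifted sets can jump across that gap. The lowest group means, -0.11 in the knockout and -0.22 in the control, are floors shared by 349 and 306 regions, and a fold against a floor is set by it. With a mean per group only, no replicate error could be computed and the depth of each library is unknown. The counts per library that the planned design assumed first were not there, so the authors' test was used as deposited, the last option of that design. Read depth enters only through the mean signal, 22.6 normalized reads in the median region.

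Regions with the authors' adjusted p under 0.05 were called gained (positive fold) or lost (negative fold). The table's transcripts were compared with GENCODE M21 on GRCm38: 31354 of 31654 were found, all with the same position, so the reference sequence of that build was used for GC content and motifs on the 65524 regions of the main chromosomes. The share gained was tested with a two-sided exact binomial test. Annotation classes, chromosomes and the gained against lost regions of each list were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment. The Fisher tests treat regions as independent. Several regions can belong to the same gene and neighbours changed the same way, so the p-values of these tests may be too small. Distances, signal and width were compared by permutation of medians (100000 resamples). Clustering was compared with 1000 shuffles of direction within chromosomes. For 20 gene lists, each gene was given the mean fold of its assigned regions, and the median over genes was compared with 10000 random lists matched on quintiles of regions per gene and of mean signal, two-sided, with Benjamini-Hochberg adjustment over the lists. Regions were assigned to genes by the authors as the nearest transcript start, which need not be the gene they act on. Counts adjusted over the list alone used Benjamini-Hochberg over the deposited p-values of a list's regions. For rescaled folds, a standard error was taken back from each deposited fold and p-value under a normal distribution. The new p-values were adjusted over the number of tests implied. Regions not analysed here could not be rescaled, so counts on rescaled folds leave them out. For 20 motif consensus strings, the share with a match in the central 200 bp was compared within 5 GC quintiles by the Mantel-Haenszel odds ratio. The start of the shifted segment of chromosome 14 was the single change point with the highest likelihood in the share of positive folds, at least 20 regions from either end. Runs of regions with the same direction were scanned on each chromosome against 100 shuffles.

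Named genes followed a rule fixed before the data were examined. It names Lmna, Nkx2-5, Gata4 and Gata6, the genes of the 8 gained and 8 lost regions with the smallest adjusted p (ties by larger fold, 1 region per gene), the 5 genes with the most gained and the 5 with the most lost regions, and in each list up to 2 members with the gained region and up to 2 with the lost region of smallest adjusted p, leaving out predicted symbols. Lists, motifs and tests were fixed at the same time. The segment of chromosome 14, leading genes outside it, scaling on strong promoters or on a running mean over 2000 regions, the run scan, and lists of imprinted and germline genes were added after the data were seen.

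The gene list test, change point, clustering test and run scan were tried on simulated data made from the table. The stratified odds ratio and the permutation of medians were tried on random draws not taken from it. The other tests and the rescaling were not simulated. For the gene lists, folds were shuffled over single regions, which removes the likeness of neighbours. The rate of false calls given next need not hold for the real data. Of 20 lists of 20 genes shifted by 0.5 log2, 15 were recovered, and 5 of 100 unshifted lists were called. The planted change point was found within a median of 1 region, 18 of 20 planted runs exceeded all of 200 shuffles, the clustering test called 0 of 20 shuffled data sets, and a planted odds ratio of 2 came back as 1.99. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives were stricter thresholds, a fold minimum, strong regions only, autosomes only, other windows, other gene summaries, whole regions for motifs, and the added settings.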

Results

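The data compare chromatin accessibility between Lmna knockout and control cardiomyocytes of the mouse. Lmna encodes lamins A and C, intermediate filament proteins of the nuclear lamina, the protein mesh under the inner nuclear membrane. E14 embryonic stem cells carrying a green fluorescent reporter of Nkx2-5, a cardiac transcription factor, were differentiated in hanging drops, and reporter-positive cells were sorted on day 10. Open chromatin in their nuclei was then profiled by ATAC-seq, in which a transposase cuts accessible DNA and adds sequencing adapters. The labels give 3 control and 3 knockout libraries and do not say whether these came from separate differentiations. Their titles name no clones, so genotype and cell line cannot be separated. The values are those of the authors' comparison of the groups, with a mean per group and no value per library, so the depth of each library is unknown and p-values reflect only the spread the authors' test saw between these samples. The table lists 65535 regions with a median width of 637 bp, ordered by the authors' p and ending at an adjusted p = 0.843. The median region had 22.6 normalized reads, with quartiles of 12.0 and 54.2. The relation of p to adjusted p implies that about 80900 regions were tested, so that about 15400 regions with higher p are not analysed here. Coordinates are those of mm10, counted from 1.

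At the Lmna gene, 2 of 4 regions were at the lowest knockout level of the table, and the other 2 did not pass the test. In the authors' deposited table, the region at chromosome 3, 88502792 to 88503754, which overlaps exon 1 of the transcript Lmna-201, had a log2 control mean of 7.11 and a log2 knockout mean of -0.11 (adjusted p = 1.77e-12). The region at 88492517 to 88493532, which overlaps exon 1 of Lmna-202, had a log2 control mean of 7.86 and the same knockout mean of -0.11 in the authors' deposited table (adjusted p = 2.48e-16). The value -0.11 is the floor of the knockout means, shared by 349 regions, so the folds of both Lmna regions depend on that floor and are not given. Of 8333 regions with a log2 control mean of at least 7, 2 were at the knockout floor, and both were these. The regions that did not pass lie at 88509511 to 88510554, in the 5' untranslated region and overlapping exon 1 of Lmna-206 (log2 means of 8.06 in control and 8.35 in knockout cells, adjusted p = 0.461 in the authors' deposited table), and at 88473113 to 88473583 (log2 fold -1.0, adjusted p = 0.241 in the authors' deposited table).

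Knockout cells had more gained than lost regions at the normalization of the table. By the authors' adjusted p under 0.05, 9337 regions differed, of which 5861 were gained (higher in the knockout) and 3476 were lost. The share gained was 62.8% (95% exact binomial interval 61.8% to 63.8%, two-sided exact binomial p = 7.18e-136 against 50%), a description that treats neighbouring regions as independent. Gained regions had a median log2 fold of 1.77 and lost regions of -1.64 in the authors' deposited table. Gained regions alone were assigned to 2803 genes, lost regions alone to 2033 genes and both kinds to 728 genes, out of 18240 genes with a region. The balance depends on the scale. Promoters within 1 kb of a start and with a log2 mean signal of at least 8 on autosomes had a median log2 fold of 0.36. With this value subtracted from every fold, 3275 regions were gained and 10955 lost, a share gained of 23.0%. Any of the regions not analysed here that would turn to lost are left out of that count. With folds less their running mean over signal, 5755 regions were gained and 3090 lost (65.1% gained), and 2807 of the 3476 lost regions stayed lost. Of the gained regions named below for a change, 1 each of Gata6 (at 11087976), Tbx18, Wnt5b, Aurka, Jun and Mirg no longer passed after subtraction of the strong promoter median. Their adjusted p-values, recomputed from the deposited fold and p under a normal distribution, were 0.0743, 0.0614, 0.0817, 0.204, 0.459 and 0.0748.

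A single chromosome segment held 17.8% of all gained regions. On chromosome 14, 1214 regions were gained and 75 lost (odds ratio 11.8 against the other chromosomes, two-sided Fisher's exact test, adjusted p = 1.57e-172). On the other autosomes, the share gained among changed regions ran from 52.4% on chromosome 4 to 73.0% on chromosome 19. Most of the excess lay in the distal part: a change point in direction fell at 75.9 Mb, and from there to the last region at 124.8 Mb, 2204 of 2284 regions (96.5%) had a higher mean in the knockout, against 52.6% of the 1846 regions before it and 48.8% on the other autosomes. Within the segment 1044 regions were gained and 4 lost. An excess remained on the rest of chromosome 14, with 170 gained and 71 lost regions (odds ratio 1.75, two-sided Fisher's exact test without the segment, adjusted p = 0.00034). It was not particular to chromosome 14. In the same test chromosomes 8, 16, 18 and 19 also passed towards gained regions (odds ratios 1.58, 1.42, 1.67 and 1.98) and chromosome 4 towards lost ones (0.78). The best run of higher means on chromosome 14 began at 74.6 Mb, so some shifted regions lie before the change point. Of the 100 regions with the smallest p, 61 lay in the distal segment. Strong promoters of the segment, those with a log2 mean signal of at least 8, had a median log2 fold of 1.43 (SD 0.40 over 61 promoters), against 0.36 (SD 0.23 over 3140 promoters) on the other autosomes.

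**Figure D1:**
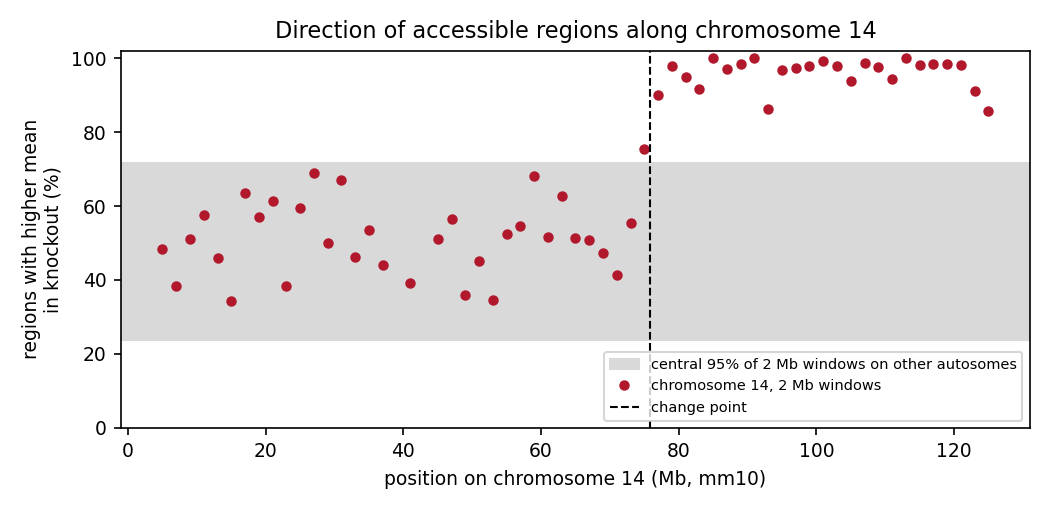
Share of regions with a higher mean in the knockout (y axis, percent) in 2 Mb windows along chromosome 14 (x axis, Mb), with the central 95% of such windows on the other autosomes shaded and the change point dashed. Windows distal of the change point at 75.9 Mb lie above the shaded range, which runs from 23.7% to 71.5%.

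The gained regions with the smallest adjusted p were on distal chromosome 14. In the authors' deposited table these were the promoters of Rap2a, a Ras-related small GTPase (120477237 to 120479279, log2 fold 1.58, adjusted p = 1.97e-35), Kbtbd7 (log2 fold 1.84), Tmtc4 (log2 fold 1.52), Sugt1 (log2 fold 1.82) and Mir5130 (log2 fold 1.54), and regions assigned to Mzt1 (log2 fold 3.13) and Mir6239 (log2 fold 2.96). The promoter of Zc3h13 (75283755 to 75285004, log2 fold 1.79 in the authors' deposited table) lies just before the change point. The genes with the most gained regions were also in the segment: Klf12 with 33, Diaph3 and Gpc6 with 30 each, and Enox1 and Farp1 with 28 each.

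Outside the segment, and after Zc3h13, the gained regions with the smallest adjusted p included those of cardiac myosins and myoglobin. The genes in this paragraph were chosen by the rule for named genes applied again without the segment, after the values were seen. In the authors' deposited table, the Myh6 promoter (alpha myosin heavy chain, chromosome 14, 54966393 to 54967206) had a log2 fold of 3.23 (adjusted p = 1.62e-15), an intergenic region upstream of Myh7 (beta myosin heavy chain) had 2.55 and a region near the start of Mb (myoglobin, chromosome 15, 77019020 to 77020130) had 3.20. Distal regions assigned to Bmp7 (log2 fold 2.37), Hif1a (log2 fold 3.21) and Rimkla (log2 fold 2.67) and the promoter of Cmtm5 (log2 fold 2.26) followed in the authors' deposited table. By number of gained regions, Slc8a1 led with 15 of its 41 regions, then Fhod3, a formin of the sarcomere, with 11 of 25, Ttn (titin) with 9 of 15, Gmpr with 9 of 20 and Cadm1 with 9 of 29. None of these 5 genes had a lost region.

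Nkx2-5, whose reporter was used for the sort, and Gata6 had gained regions and no lost ones, while Gata4 had both. Nkx2-5 had 2 gained regions of 3 in the authors' deposited table, its promoter (chromosome 17, 26841203 to 26842133, log2 fold 1.24, adjusted p = 0.00263) and a region at 26868712 to 26869232 (log2 fold 1.78, adjusted p = 0.00703). Gata6, a cardiac and endodermal zinc-finger factor, had 4 gained regions of 11 in the authors' deposited table, 1 of them starting at 11087976, and the one of smallest p 85682 bp from its start (chromosome 18, 11144729 to 11145586, log2 fold 2.77, adjusted p = 2.90e-14), while its promoter had a log2 fold of 0.46 (adjusted p = 0.218). Gata4 had a gained promoter region (chromosome 14, 63271519 to 63271853, log2 fold 1.97, adjusted p = 0.00313), a lost intergenic region (63281159 to 63281488, log2 fold -2.89, adjusted p = 0.0171) and 10 regions that did not pass, in the authors' deposited table. The lost region was weak, with a log2 mean signal of 2.74 and a log2 knockout mean of 0.67, near the floor of -0.11. The cardiac transcription factor list as a whole lay within the range of random lists, with a median log2 fold of 0.13 over 21 measured genes (95% range of matched random lists -0.27 to 0.28, adjusted p = 0.444). Of these genes, 8 had only gained, 3 only lost, 6 both and 4 no changed regions. Besides Gata6, the leading gain was at Tbx5 (log2 fold 2.69), and the leading losses at Prdm16 (log2 fold -1.37) and Irx4 (log2 fold -1.50), in the authors' deposited table.

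The sarcomere, calcium-handling and energy metabolism lists lay above random lists. Each list was compared with 10000 random lists matched on regions per gene and mean signal, using folds from the authors' deposited table, a comparison that a shift of all folds leaves as it is. The sarcomere and myofibril list had a median log2 fold of 1.32 over 25 genes (random lists -0.29 to 0.22, adjusted p = 0.0013, from a permutation p = 0.0002, the smallest that 10000 random lists can give). All 25 genes had a gained region, and 2, Myl3 and Nebl, had a lost region too. Of their 139 regions, 63 were gained and 3 lost, or 75 and 4 adjusted over the list alone. After subtraction of the strong promoter median, the only gained regions of 2 of the 25 genes no longer passed (recomputed adjusted p = 0.228 and 0.0911). The calcium-handling and ion channel list had a median of 0.79 over 27 genes (adjusted p = 0.0013), with 69 gained and 9 lost of 246 regions, or 92 and 15 adjusted over the list alone. Its leading gains were at the promoter of Slc8a1, the sodium-calcium exchanger (chromosome 17, 81737568 to 81738712, log2 fold 2.44), and upstream of Atp2a2, the calcium pump of the sarcoplasmic reticulum (log2 fold 1.80), and its leading losses at Cacna2d1 (log2 fold -1.56) and Kcnj3 (log2 fold -1.93), in the authors' deposited table. By promoter regions only, this list's median was 0.34 and did not pass (adjusted p = 0.223, against 0.0013 to 0.015 under its other alternatives). The energy metabolism list had a median of 0.54 over 24 genes (adjusted p = 0.0013), with 22 gained and 2 lost of 90 regions, or 24 and 2 adjusted over the list alone. Its shift towards gained regions relative to all changed regions (odds ratio 6.54, two-sided Fisher's exact test, adjusted p = 0.0076) did not pass among regions of adjusted p under 0.01 (odds ratio 4.02, adjusted p = 0.403, against 0.0029 without the segment). Here 11 genes had only gained, 1 only lost, 1 both and 11 no changed regions, with leading gains at Cox6a2, a muscle subunit of cytochrome c oxidase (log2 fold 3.92 at its promoter), and Esrrg (log2 fold 1.94), and losses at Slc2a1 (log2 fold -1.26) and Esrrg (log2 fold -1.99), in the authors' deposited table.

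**Figure D2:**
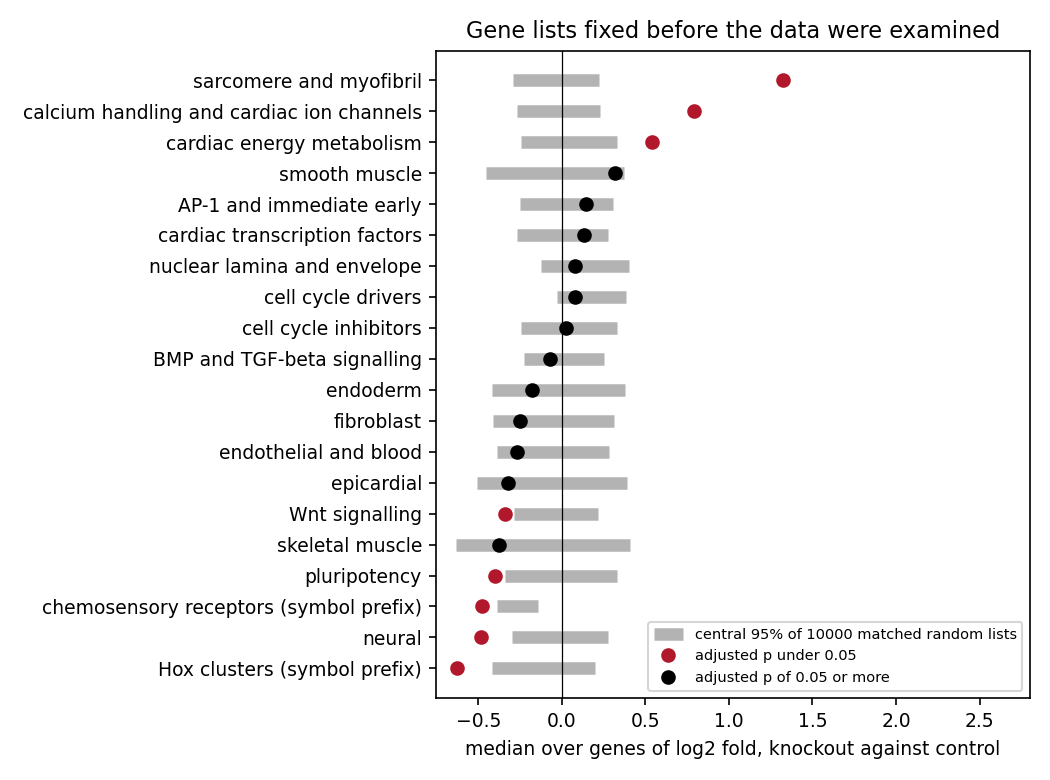
Median over genes of the log2 fold of knockout against control (x axis) for each gene list (y axis). Points are the lists, red where the adjusted p is under 0.05, and grey bars are the central 95% of 10000 matched random lists; the sarcomere list lies at 1.32 and the Hox list at -0.63.

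The Hox, neural and chemosensory receptor lists lay below random lists. The Hox cluster genes had a median log2 fold of -0.63 over 37 genes (random lists -0.42 to 0.20, adjusted p = 0.0020), with 6 lost and no gained regions, or 4 and 0 adjusted over the list alone. The leading losses were at Hoxb6 (log2 fold -1.39) and Hoxd3 (log2 fold -1.08) in the authors' deposited table. Random lists were drawn from genes over the whole genome, whereas Hox cluster genes and some chemosensory receptor genes are neighbours. Neighbouring regions changed the same way (below), so the members of these lists are not independent. The adjusted p of both lists may therefore be too small. The neural list had a median of -0.49 over 22 genes (adjusted p = 0.0032), with 7 gained and 15 lost regions, or 8 and 16 adjusted over the list alone. Neurog2, a proneural transcription factor, had a log2 fold of -0.98 and Dcx, a microtubule protein of young neurons, of -3.26, against gains at Syt1 (2.13) and Ncam1 (1.97) in the authors' deposited table. The log2 knockout mean of the Dcx region was 0.67, near the floor of -0.11. The chemosensory receptor genes had a median of -0.48 over 248 genes (random lists -0.39 to -0.14, adjusted p = 0.0033), with 5 gained and 26 lost regions, or 5 and 21 adjusted over the list alone. Their leading losses were at Olfr294 (log2 fold -3.56, with a log2 knockout mean of 0.65, also near the floor) and Vmn2r17 (-1.37) and their leading gains at Vmn2r3 (3.06) and Olfr1505 (2.41) in the authors' deposited table. With each gene taken by its region of smallest p, the neural (adjusted p = 0.215) and chemosensory (0.191) medians did not pass, nor did the chemosensory median by promoter regions only (0.646), while their adjusted p was 0.0040 or lower under the other alternatives.

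The medians of the pluripotency and Wnt lists lay below random lists, but did not pass without the distal segment of chromosome 14. The pluripotency list had a median log2 fold of -0.40 over 18 genes (adjusted p = 0.046, and 0.062 without the segment), with 18 gained and 6 lost regions, or 22 and 11 adjusted over the list alone. Of the gained regions, 14 belonged to Klf5, which lies in the segment (promoter log2 fold 1.53 in the authors' deposited table). Sall4 (log2 fold -2.36) and Dppa4 (log2 fold -2.12) led its losses, and Klf2 (log2 fold 2.31) was gained, in the authors' deposited table. The Wnt list had a median of -0.34 over 28 genes (adjusted p = 0.038, and 0.062 without the segment), although none of its regions lie there and only the random lists change. It had 7 gained and 19 lost regions, or 9 and 24 adjusted over the list alone. Relative to all changed regions it was shifted towards lost regions (odds ratio 0.22, two-sided Fisher's exact test, adjusted p = 0.0015), and this passed among regions of adjusted p under 0.01 (odds ratio 0.0452, adjusted p = 0.0012) and without the segment (odds ratio 0.26, adjusted p = 0.0084). In the authors' deposited table, it had losses led by Axin2, a target and inhibitor of the pathway (log2 fold -1.52), and Wnt5b (-1.31), and gains by Wnt11 (1.78) and Wnt5b (1.38). With each gene taken by its region of smallest p, neither median passed (adjusted p = 0.191 and 0.102), and under the other alternatives with the segment included both did (0.0013 to 0.042).

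The remaining markers of other cell types did not pass the test against random lists by their medians over all regions. The medians were -0.18 for endoderm (adjusted p = 0.558), -0.27 for endothelium and blood (0.444), 0.32 for smooth muscle (0.201), -0.25 for fibroblasts, which also serve as feeder cells (0.444), -0.32 for epicardium (0.444) and -0.38 for skeletal muscle (0.515). Gained and lost regions numbered 8 and 13 for endoderm, 6 and 6 for endothelium and blood, 10 and 2 for smooth muscle, 3 and 10 for fibroblasts, 2 and 6 for epicardium and 3 and 6 for skeletal muscle. Adjusted over the list alone, they numbered 12 and 16, 6 and 6, 10 and 2, 4 and 12, 3 and 8, and 3 and 8, in the same order. Relative to all changed regions, the endoderm list was shifted towards lost regions (odds ratio 0.36, two-sided Fisher's exact test, adjusted p = 0.047, and 0.139 without the segment of chromosome 14 and 0.403 among regions of adjusted p under 0.01). The fibroblast list was shifted the same way (odds ratio 0.18, two-sided Fisher's exact test, adjusted p = 0.015), with losses at Col3a1 (log2 fold -1.86) and Prrx1 (-0.72) and gains at Thy1 (2.03) and Fbn1 (2.60) in the authors' deposited table; at adjusted p under 0.01 this shift did not pass (odds ratio 0.364). In the endoderm list, Foxa2 had a lost region (log2 fold -2.10) and a gained one (1.81), Cxcr4 likewise (-2.42 and 3.69) and Prox1 too (-2.03 and 2.24) in the authors' deposited table. Kdr and Flt1, receptors of vascular endothelial growth factor, had lost regions (log2 fold -2.14 and -2.40), Erg a gained one (2.20), and Pecam1 a gained (1.87) and a lost one (-1.57), in the authors' deposited table. Pax3 and Pax7 of skeletal muscle precursors had lost regions (log2 fold -1.24 and -1.54), and the myogenic factors Myf6 and Myog gained ones (2.11 and 2.04), in the authors' deposited table. Gains in smooth muscle genes were led by Lmod1 (log2 fold 2.30) and Synpo2 (1.57), with a loss at Mylk (-2.03), in the authors' deposited table. By promoter regions only, endoderm (-0.57), endothelium and blood (-0.66) and fibroblasts (-0.51) passed below random lists and smooth muscle (0.46) above them. In the epicardial list, Tbx18 had a gained region (log2 fold 1.04) and a lost one (-2.30), and Sema3d a lost one (-2.42), in the authors' deposited table.

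The cell cycle, nuclear envelope, BMP and TGF-beta, and AP-1 lists had medians within the range of random lists. Cell cycle drivers had a median of 0.08 over 26 genes (adjusted p = 0.297), but 4 gained and 14 lost regions, or 7 and 14 adjusted over the list alone, a shift towards lost regions (odds ratio 0.17, two-sided Fisher's exact test, adjusted p = 0.0031) that did not pass among regions of adjusted p under 0.01 (odds ratio 0.364). Mycn, a proliferation factor of progenitors, had 7 of these lost regions, the most of any gene, led by one at chromosome 12, 12724982 to 12726092 (log2 fold -2.43 in the authors' deposited table). By gene, 4 drivers had only lost, 1 only gained, 2 both and 19 no changed regions. The Fisher test, which counts regions as independent, thus rests on few genes. Mki67 also led the losses (log2 fold -2.85), and Ccne1, which drives entry into DNA replication, and Aurka, a mitotic kinase, led the gains (2.74 and 0.72), in the authors' deposited table. Cell cycle inhibitors had a median of 0.03 (adjusted p = 0.876) with 8 gained and 11 lost regions, or 10 and 11 adjusted over the list alone, including gains at Btg2 (log2 fold 1.96) and Meis1 (2.49) and losses at Cdkn1c (-1.63) and Rb1 (-1.46) in the authors' deposited table. The nuclear lamina and envelope list had a median of 0.08 (adjusted p = 0.444) with 7 gained and 4 lost regions, of which 2 are those of Lmna, or 8 and 5 adjusted over the list alone. Sun2, which links the lamina to the cytoskeleton, was gained at its promoter (log2 fold 1.86), and Lmnb1, which encodes lamin B1, had a gained (1.79) and a lost (-1.85) distal region in the authors' deposited table. BMP and TGF-beta genes had a median of -0.07 (adjusted p = 0.558) with 12 gained and 13 lost regions, or 13 and 15 adjusted over the list alone, among them gains at Bmp7 (2.37) and Bmp10 (2.12) and losses at Smad2 (-1.29) and at Bmp2, whose knockout mean was at the floor, in the authors' deposited table. AP-1 and immediate early genes had a median of 0.15 (adjusted p = 0.50) with 4 gained regions, led by Fos (log2 fold 1.92) and Jun (0.60), and 1 lost, at Nr4a1 (log2 fold -1.19), in the authors' deposited table, or 1 and 0 adjusted over the list alone.

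Among genes with lost regions, the smallest adjusted p after Lmna was at the promoter of Mest, an imprinted gene of embryonic mesoderm. In the authors' deposited table it had a log2 fold of -3.65 (chromosome 6, 30736229 to 30738360, adjusted p = 6.81e-15). Next by adjusted p in the authors' deposited table were distal regions assigned to Epha3 (log2 fold -2.73) and Stx16 (log2 fold -1.61), the promoter of Msh4, a meiotic recombination gene (log2 fold -1.69), and regions assigned to Slc2a3 (log2 fold -2.31), Ran (log2 fold -2.39) and Rubie (log2 fold -2.15). After Mycn, the most lost regions belonged to Cdh11 (6 of 18), Macrod2 (6 lost and 5 gained of 42), Wscd2 (6 of 13) and Zic4 (5 lost and 1 gained of 15). Of the genes named above for a change in a single direction, Bmp7, Btg2, Ccne1, Meis1 and Syt1 also had lost regions, and Mki67, Rb1, Smad2, Cacna2d1, Prdm16 and Irx4 also had gained ones.

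Gained regions lay in introns more often than lost ones. Introns held 40.1% of gained and 29.8% of lost regions, against 32.1% of all regions (odds ratio gained against lost 1.58, two-sided Fisher's exact test, adjusted p = 4.89e-23). Distal intergenic regions made up 29.7% of gained and 36.5% of lost regions (odds ratio 0.73, adjusted p = 4.03e-11). Promoters were rarer among gained (23.0%) and lost (21.3%) regions than among all regions (28.7%), and the comparison of gained and lost did not pass (odds ratio 1.10, adjusted p = 0.064), but passed for promoters within 1 kb (odds ratio 1.41, adjusted p = 2.50e-08). Without the segment of chromosome 14, promoters were more frequent among gained than lost regions (25.1% against 21.3%, odds ratio 1.24, adjusted p = 9.2e-05). Exons, 3' untranslated regions, 5' untranslated regions and downstream regions were each more frequent among lost regions, with odds ratios of 0.71, 0.45, 0.24 and 0.35. At adjusted p under 0.01, exons (0.85) and 5' untranslated regions (0.36) did not pass. Gained and lost regions lay at similar distances from the nearest transcript start, with medians of 17800 bp and 17414.5 bp (permutation test, two-sided p = 0.619). Without the segment, gained regions were nearer by 0.08 in median log10 distance (p = 0.00083, permutation test). Lost regions were wider, with a median of 817.5 bp against 574 bp, and slightly weaker, with a median log2 signal of 4.47 against 4.67 in the authors' deposited table (permutation tests, two-sided p = 1e-05 each, the smallest 100000 resamples can give).

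**Figure D3:**
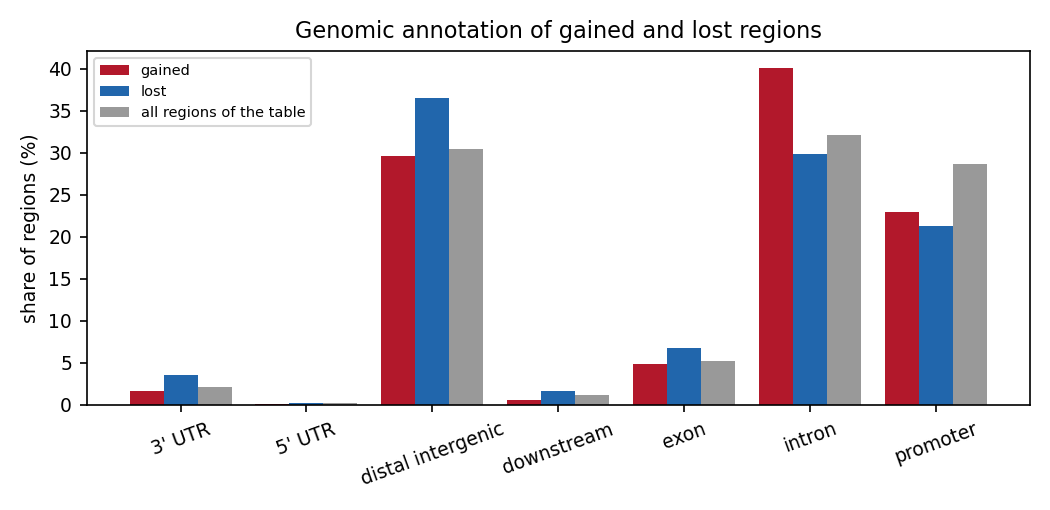
Share of regions (y axis, percent) in each annotation class (x axis) for gained regions (red), lost regions (blue) and all regions of the table (grey). Introns hold 40.1% of gained and 29.8% of lost regions.

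Neighbouring regions changed the same way. Among 4532 pairs of adjacent changed regions within 100 kb, 74.2% went the same way, against 60.1% on average when directions were shuffled within chromosomes (permutation p = 0.001, the smallest 1000 shuffles can give). Without the segment the share was 67.8% of 3611 pairs, against 51.9% when shuffled.

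The consensus strings of MEF2, AP-1, NKX2, GATA, MEIS and TEAD factors were more frequent in gained than in lost regions. Consensus strings were searched on both strands in the central 200 bp and compared within quintiles of GC content. The MEF2 consensus was in 288 of 5860 gained regions (4.91%) and 8 of 3475 lost regions (0.23%), an odds ratio of 23.4 (95% interval 11.5 to 47.8). AP-1 was in 12.5% and 2.91% (odds ratio 4.76, 3.85 to 5.89), NKX2 in 9.71% and 4.43% (2.34, 1.94 to 2.81), GATA in 28.4% and 18.2% (1.85, 1.66 to 2.05), MEIS in 4.78% and 2.5% (1.95, 1.53 to 2.49) and TEAD in 9.69% and 6.39% (1.57, 1.33 to 1.84). The rarer SRF CArG (odds ratio 3.15), ETS (3.04) and KLF/SP (1.34) strings were also more frequent in gained regions. RFX (odds ratio 0.25), SOX (0.52), PITX/OTX (0.60), FOX (0.68) and the HAND E-box (0.85) were more frequent in lost regions. CTCF, TBX, E-box, octamer, NFY and NRF1 did not pass in the central 200 bp, and of these CTCF passed without the segment (0.21). Over whole regions, of which the lost ones are wider, the odds ratios of TEAD (0.90), KLF/SP (0.85), TBX (0.78), NFY (0.77) and E-box (0.66) turned and passed, and that of GATA (0.94) turned without passing. Those of NKX2 (1.09) and MEIS (1.05) no longer passed over whole regions, and CTCF (0.41), octamer (0.44) and NRF1 (3.18) did. At adjusted p under 0.01, SRF, ETS, KLF/SP and the HAND E-box did not pass. Examples of MEF2 matches in gained regions are CTATTTTTAG at chromosome 7, 128206406 to 128206415, in the Cox6a2 promoter region, with the surrounding sequence ACATGGATGGCTATTTTTAGGGGCTTTCTC, and CTAAATTTAG at chromosome 2, 76982704 to 76982713, in a region annotated as a Ttn promoter, with the surrounding sequence ATTGGCAGTGCTAAATTTAGCCTTTCAGAA. A GATA match, AGATAA, lies at chromosome 5, 119964924 to 119964929, in the gained intergenic region of Tbx5.

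**Figure D4:**
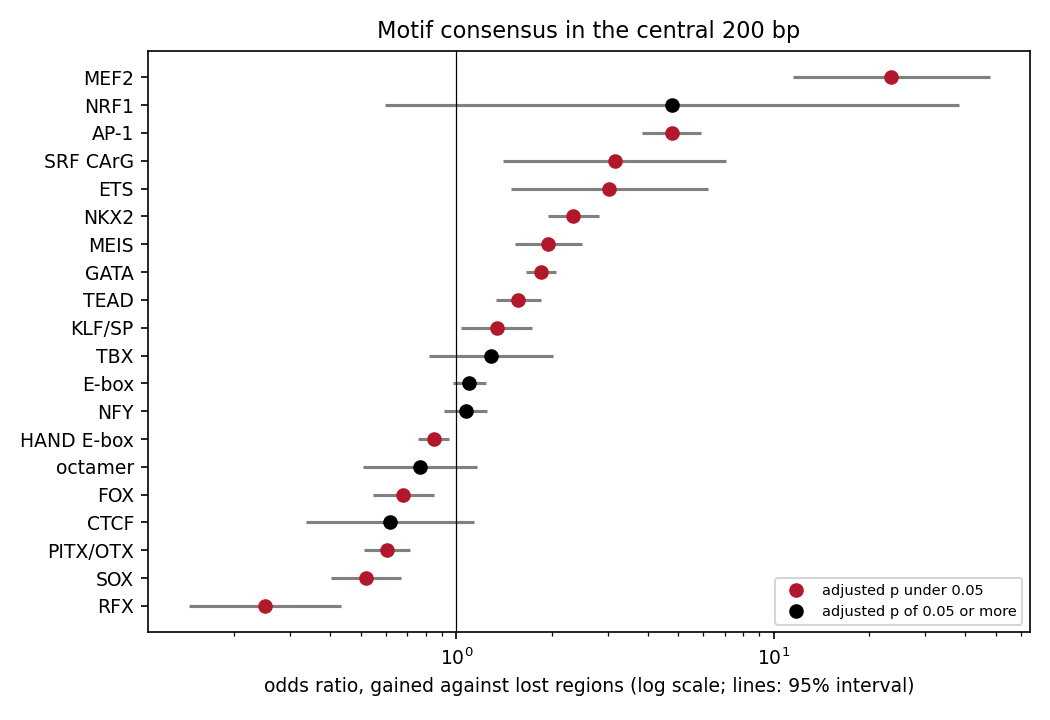
Odds ratio of a motif match in the central 200 bp of gained against lost regions (x axis, log scale) for 20 consensus strings (y axis), with 95% intervals as lines and red points where the adjusted p is under 0.05. MEF2 has the highest odds ratio, 23.4, and RFX the lowest, 0.25.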

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

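The settings without the distal segment of chromosome 14, the rescaled folds and the number of tests for Bonferroni were chosen after the data were seen. No paired analysis was possible because the table holds means per group and no value per library. For the same reason other normalizations, a DESeq2 test, low-count filters, pseudocounts, leaving out replicates and other splits of the samples were not run. Bonferroni was planned over a table of all regions and was run over the number of tests implied, giving 822 changed regions (749 gained, 73 lost). Of 238 values under alternatives, 167 kept their direction and side of the threshold, or a count within 1.5 times. Except where stated, the cause was not tested for the values that follow. Adjusted p under 0.01 gave 3939 changed regions (2887 gained, 1052 lost) and under 0.001 gave 1624 (1379 and 245), by construction fewer. Regions above the median signal numbered 4885 (3183 and 1702). Folds less the strong promoter median gave 14230 (3275 and 10955), 23.0% gained, which reverses the balance by moving 0.36 from every fold.

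At adjusted p under 0.01, with fewer regions, odds ratios of annotation were 0.36 for 5' untranslated regions, 0.85 for exons (neither passing) and 0.89 for promoters (reversed). Distance differed by -0.0260 (reversed, not passing), and 10 chromosomes passed. For lists, the odds ratios no longer past the threshold were 4.02 for energy metabolism, 0.364 for cell cycle drivers, endoderm, neural and fibroblast, and 0.22 for chemosensory receptors, and those on the other side of 1 were 0.97 for cardiac factors, 0.364 for lamina and envelope and 1.002 for BMP. For motifs, they were 0.90 for the HAND E-box, 7.66 for SRF, 6.36 for ETS and 1.13 for KLF/SP, no longer passing, and 2.21 for CTCF and 0.89 for NFY, reversed and not passing.

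Without the segment, promoters passed with an odds ratio of 1.24, distance differed by -0.0782 (reversed, passing), 6 chromosomes passed, CTCF passed at 0.21, and pluripotency (-0.40) and Wnt (-0.34) medians no longer passed. Pluripotency regions turned to an odds ratio of 0.48, since Klf5 leaves, and endoderm, at 0.44, no longer passed. Promoters within 1 kb passed at 1.41. By promoter regions only, medians passed for endoderm (-0.57), endothelium and blood (-0.66), smooth muscle (0.46) and fibroblast (-0.51), no longer for calcium handling (0.34) and chemosensory receptors (-0.42), and turned against random lists for cardiac factors (0.16) and lamina and envelope (0.33). Within 50 kb, endothelium and blood (-0.48) and fibroblast (-0.51) passed. By the region of smallest p, medians of pluripotency (-0.87), neural (-0.72), Wnt (-0.94) and chemosensory receptors (-0.55) no longer passed, and BMP (0.49) turned. Over whole regions, of which lost ones are wider and so hold more chance matches, GATA (0.94), TEAD (0.90), TBX (0.78), E-box (0.66), KLF/SP (0.85) and NFY (0.77) reversed, all but GATA passing, NKX2 (1.09) and MEIS (1.05) no longer passed, and CTCF (0.41), octamer (0.44) and NRF1 (3.18) passed. The depth of the libraries is unknown, so its effect could not be measured.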

Other observations

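Imprinted and germline genes were noticed among the lost regions, and lists of both were then made. Tests chosen only after results were seen are those of the imprinted and germline lists, the run scan, the strong promoters of the segment, the gene-poor windows, the comparison at matched signal, the blocks of other autosomes, the repeated bootstrap draws, the promoters within 1 kb of a start in the segment and the count of list regions in the segment. The members of both lists had been seen among lost regions, so their values are not independent evidence. Of 43 imprinted genes with a region, 18 had only lost, 4 only gained, 3 both and 18 no changed regions, with 30 lost and 10 gained regions in all (odds ratio 0.20, two-sided Fisher's exact test, adjusted p = 2.90e-06 over the 2 lists). Besides Mest, losses in the authors' deposited table were at Mkrn3 (log2 fold -2.45), Magel2 (-1.82) and Igf2 (-1.69) and a gain at Plagl1 (1.71). Mirg of the Dlk1 to Dio3 domain had 1 lost (log2 fold -3.25) and 1 gained region (1.93), and Grb10 had 3 gained (led by 2.18) and 1 lost (-1.19), in the authors' deposited table. With the strong promoter median subtracted, the gained region of Mirg did not pass (adjusted p = 0.0748). Of 23 germline genes, 5 had only lost regions, 1 only a gained one, 1 both and 16 no changed regions, with losses at Msh4 (log2 fold -1.69), Ldhc (-2.32) and Sycp3 (-2.20) and a gain at the promoter of Mov10l1 (1.81) in the authors' deposited table.

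Shorter blocks of neighbouring regions moved together on other chromosomes. A scan looked for the best run in each direction on 20 chromosomes, and 25 of the 40 runs scored above all 100 shuffles. The run with the most regions after chromosome 14 was on chromosome 4 from 145.1 to 147.8 Mb, where 88.7% of 106 regions, among them those assigned to Zfp982 and Rex2, had a lower mean in the knockout. On chromosome 11, 94.9% of 39 regions from 96.1 to 96.8 Mb at the Hoxb cluster and Skap1 were lower. Runs of higher means covered Ryr2 and Actn2 on chromosome 13 (92.0% of 50 regions), Lpp on chromosome 16 (100% of 32 regions), Myocd on chromosome 11 (92.3% of 39 regions) and Ttn on chromosome 2 (90% of 40 regions).

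The excess of gained regions on chromosome 14 was weighed against several explanations, and a copy number difference of the whole chromosome is argued against by 53.8% of its 10 Mb windows, whose share of higher means lay within the range of the other autosomes, and opening of gene-poor domains on all autosomes alike by the 20 windows elsewhere with as few genes per Mb as the segment, of which the highest had 60.2% higher means against at least 95.1% in the segment. Opening of gene-poor chromatin on chromosome 14 alone stays open. The segment had 2.11 protein-coding genes per Mb against 8.52 elsewhere and 8.45% promoters against 29.3%. Strong promoters lay 1.07 (95% bootstrap interval 0.97 to 1.15) above other autosomes in the segment. Over the whole chromosome they lay 0.23 (0.16 to 0.33) above, around the limit of 0.3 set beforehand. That value cannot decide, because it pools the 61 of the segment with 80 before it, whose median log2 fold was 0.43. The values in the segment argue against an opening that spares strong promoters, but not against an opening of the whole segment. A copy number difference of the distal segment is a candidate explanation, although the planned comparison of promoter, intronic and intergenic regions differed by 0.71 (0.61 to 0.82), above the limit of 0.5 set beforehand to exclude it. That limit may not apply, because the classes differ in signal (median log2 signal 6.05 in promoters and 3.58 in intergenic regions). At matched signal from 4 up, their mean folds differed by 0.0717 (0.0239 to 0.275), and with weaker regions included by 0.125 (0.0315 to 0.286). The planned comparison used median folds. Whether the matching or the change from medians to means made the range smaller cannot be told apart, so the planned result is not set aside. Whether the control line lost or the knockout line gained cannot be told apart. Control promoters of the segment lay at -1.11 against other autosomes, below all 55 blocks of up to its length elsewhere (-0.50 to 0.49). This was beyond the planned limit of -0.25 in 20 of 20 sets of bootstrap draws (upper bounds -0.72 to -0.28). Knockout promoters lay at -0.08, within those blocks (-0.67 to 0.62), as a loss in the control would give. However, the segment lists 1.87 promoter regions per protein-coding gene against 0.88 elsewhere. By promoters within 1 kb of a start, the control lay at -0.10 (-0.64 to 0.68). The knockout lay at 1.17 (0.10 to 1.76) by these, above all 53 blocks (-0.59 to 0.49), as a gain in the knockout would give. Strong promoters, also planned, had a control mean 0.03 (-0.09 to 0.11) above other autosomes. They decide nothing because they are chosen by the mean of both groups. Their shift of 1.07 was larger than the log2 value of 0.585 for 3 copies against 2.

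The sarcomere and calcium-handling lists lay above random lists, and extra signal from the segment of chromosome 14 is argued against, since 0 of the 385 regions of both lists lie in it. For that reason the planned comparison without the segment could not move the medians, of which the lower was 0.79 either way, and decides nothing. A higher share of cardiomyocytes among the sorted knockout cells could also raise these lists. It was predicted beforehand to lower markers of every other cell type. The prediction holds only for markers that cardiomyocytes do not share, and this was not checked for the lists, smooth muscle included. Of 8 such lists, 7 had medians below the median of random lists, of which neural and pluripotency passed over all regions, the latter not without the segment, and with promoter regions alone neural (-0.46), pluripotency (-0.44), endoderm (-0.57), endothelium and blood (-0.66) and fibroblasts (-0.51) did, while smooth muscle lay above and passed by promoter regions only (0.46, adjusted p = 0.048, against 0.164 to 0.191 under its other alternatives). This cannot be told apart from a change within cardiomyocytes, the biological explanation the genotype gives. The lists below go with a higher share, while smooth muscle, the list above, passed in a single setting. The sort on the Nkx2-5 reporter limits but need not remove other cells. Nor can an effect of the genotype be told apart from another difference between the lines, because the sample titles name no separate clones. That limit holds for every comparison of knockout and control here.

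The hypothesis that loss of a lamina protein may open gene-poor surroundings was tested outside chromosome 14. Distal gained and lost regions both had a median of 13 protein-coding genes within 1 Mb, a difference of 0 (95% bootstrap interval -1 to 1 over 1237 gained and 1244 lost regions). The permutation p = 1 decides nothing, because with a difference of 0 every shuffle counts. The outcome set beforehand against the hypothesis was a gained median equal to or above the lost one, and the equal medians met it. The interval still allows a difference of 1 gene either way. The means, which were not tested, were 17.4 genes near gained and 18.8 near lost regions. Only a small difference therefore stays open. The test gave no difference for the GC content of the regions to account for, and 0 of 5 GC quintiles could keep its sign.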
